A study of Homo sapiens with 6 samples.

How the data were processed

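RNA was measured in 6 samples of the BE(2)-C neuroblastoma line, 3 treated with DMSO and 3 with 10 µM NCT-503 for 2 days, and the labels describe them as independent samples. Per the labels' protocols, total RNA was labelled with a whole-transcript terminal labelling kit and hybridised to Affymetrix arrays, 1 biotin-labelled sample per array. Nothing in the labels says whether the 3 samples of a group were separate cultures, so p-values measure the spread between these samples. The authors processed the arrays with Partek, per the submitters' processing notes; its version, the background correction, the summarisation and the normalization are not given in the sources used here.

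The deposited values were taken as log2 values, because they ran from 0.578 to 13.6 with array medians near 4.3 and had no missing cells. They were not centred per gene, and their normalization stays unknown. Medians were 4.31, 4.30 and 4.30 for DMSO a, b and c and 4.32, 4.32 and 4.33 for NCT-503 a, b and c, while upper quartiles differed between arrays, so the arrays were not identical in distribution over these rows. The number of arrays limits the precision: the median SE of a log2 change was 0.105. Scanner values were not used here, so no probe could be set against its background, and folds of dim genes, such as MT1G in DMSO, may be understated.

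The table held 31135 rows. The platform annotation given here paired 15098 rows with 1 gene symbol and none with several, and all 15098 were matched by Entrez identifier to the reference table of assembly GRCh38.p14. The other 16037 rows have no name here and entered only an alternative. Where a gene had several rows (256 genes), the row with the highest mean over the 6 arrays was used, which left 14779 genes. In 4 of the 256 genes rows were called in opposite directions, and in 64 some rows were called and others not. No coordinates are given, because the build behind the array's annotation is not given in the sources used here; the reference table served only for names, gene classes, chromosomes and neighbours.

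Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, both groups in 1 fit without covariates), two-sided, with Benjamini-Hochberg adjustment over 14779 genes and calls at an adjusted p under 0.05. A fold is 2 to the power of the log2 change. Gene lists were tested with limma's camera (preset inter-gene correlation of 0.01, at least 5 measured members), with adjustment over the 34 lists tested. Beside it stand camera with an estimated correlation and fry, both adjusted the same way, and the members called when p-values were adjusted over the list alone.

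Groups, tests, the 40 gene lists and the rule for named genes were fixed before the data were examined. Of the 40 lists, 34 were tested, 4 had 1 to 4 measured members, and 2, amino acid transporters and replication-dependent histones, had none and were not analysed here. The rule names the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, leaving out small RNA, LOC, LINC, orf and other unnamed loci. It names PHGDH, PSAT1, PSPH, SHMT1, SHMT2, ATF4 and ASNS in any case, and up to 4 called members with the largest absolute change per list. Further genes of that rule were not analysed here. Members beyond the rule were named, after their values were seen, to complete counts of 5 or fewer, to name members that went against their list and to give values of members that did not pass.

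The steps were tested on simulated data built from the real means and spreads of the 14779 genes with 200 changed genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, limma recovered 23.9%, 86.6% and 97.0%, and 1 of 139 calls was false. Far more genes, 4953, were called in the real data, and the adjustment depends on that share, so these rates need not hold there. With 1 list shifted, camera called it and no other list. With no list shifted, it called 0 of 34; the simulation draws genes independently, so it does not test correlated lists.

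Alternatives fixed beforehand were eBayes with trend and robust settings, no moderation, array weights, a replicate block, centring on each array's median or 75th percentile, quantile normalization, filters at the 25th and 50th percentile of mean level, the mean of all rows of a gene, every row of the table, leaving out each array, an adjusted p under 0.01, and 3 other list tests. Testing protein-coding genes alone was added after seeing the data. Figures were drawn from the same values.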

Results

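Gene expression was measured in BE(2)-C, an established human neuroblastoma cell line, after 2 days with the vehicle DMSO or with 10 µM NCT-503. NCT-503 is a small-molecule inhibitor of PHGDH, phosphoglycerate dehydrogenase, the enzyme that opens the serine synthesis pathway. Total RNA from 3 independent samples per group was hybridised to 6 single-colour Affymetrix whole-transcript arrays, 1 array per sample. The number of arrays limits the precision. Array medians over all rows lay between 4.30 and 4.33 on the deposited log2 scale. In all, 14779 genes had a named row and were tested. Changes are log2 differences, NCT-503 minus DMSO, with limma's standard error (SE) over 3 arrays per group, and adjusted p-values are Benjamini-Hochberg values from limma over the genes tested unless stated otherwise.

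The comparison asked which transcripts differ after 2 days with NCT-503; PHGDH activity and serine were not measured here. In NCT-503-treated cells, metallothionein transcripts rose by up to 196-fold, and genes of the amino acid response (GDF15, DDIT3, ASNS, ATF5) rose by at least 6.03-fold. PHGDH itself rose 1.96-fold. Of the genes measured, 29 of 32 of DNA replication and 35 of 46 of mitosis fell, PCNA by 2.04 on the log2 scale and MKI67 by 1.17, and neither list was called with an estimated correlation (adjusted p = 0.0513 and 0.0676). The largest fall among the genes that the naming rule covers was that of MINAR2, from 7.65 ± 0.09 to 3.89 ± 0.04 (mean ± SD of log2 values, n = 3 each).

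At an adjusted p under 0.05, 2419 genes (16.4%) were higher and 2534 (17.1%) were lower with NCT-503. Of these, 733 were higher and 1310 were lower by at least 1.5-fold, and 157 and 473 by at least 2-fold; with each array centred on its 75th percentile, the counts at 1.5-fold were 1045 higher and 1076 lower. Higher calls made up 48.8% of all calls on the deposited scale. They made up 60.4% (3345 higher, 2189 lower) with that centring, which used the percentile over the genes tested. Over all 31135 rows, named or not, the 75th percentile lay between 6.03 and 6.08 in the NCT-503 arrays and between 6.16 and 6.19 in the DMSO arrays. The first principal component over all rows held 68.3% of the variance and separated the groups. Pearson correlations across all rows were 0.990 to 0.993 within groups and 0.971 to 0.972 between groups.

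Metallothioneins are small cysteine-rich proteins that bind zinc and copper. Of 10 measured members of the metallothionein and zinc response list, 8 rose, both over all genes tested and adjusted over the list alone. MT1G rose from 3.37 ± 0.23 to 10.98 ± 0.04 (mean ± SD, n = 3), a change of 7.61 ± 0.12 (SE, adjusted p = 2.76e-07). MT1F rose 44.4-fold, MT1X 41.8-fold, MT2A 7.26-fold and MT1H 4.84-fold. The 2 members that did not pass were MT3, the brain-type metallothionein, with a change of 0.12, and MTF1, the zinc-sensing factor that drives metallothionein genes, with 0.04. The list was called higher by camera (median change 2.17, adjusted p = 4.99e-07), and its adjusted p was 0.100 with an estimated correlation. Metallothionein genes are close paralogs, so their probes may not separate them.

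Serine synthesis runs from PHGDH through PSAT1 and PSPH, and the hydroxymethyltransferases SHMT1 and SHMT2 turn serine into glycine. PHGDH rose by 0.97 ± 0.09 (SE, adjusted p = 0.000299) and PSAT1 by 0.73 ± 0.07 (adjusted p = 0.000402). Mitochondrial SHMT2 rose by 1.11 ± 0.07, whereas cytosolic SHMT1 fell by 0.74 ± 0.08. PSPH rose by 0.25 ± 0.08 (adjusted p = 0.0469), and this call was lost when any 1 of the 6 arrays was left out (adjusted p from 0.0748 without DMSO b to 0.142 without DMSO a). In all, 7 of 13 measured members of the serine and glycine list rose and SHMT1 fell, and 8 rose and SHMT1 fell when adjusted over the list alone. Camera did not call the list (median change 0.28, adjusted p = 0.0712, and an adjusted p of 0.266 with an estimated correlation).

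**Figure D1:**
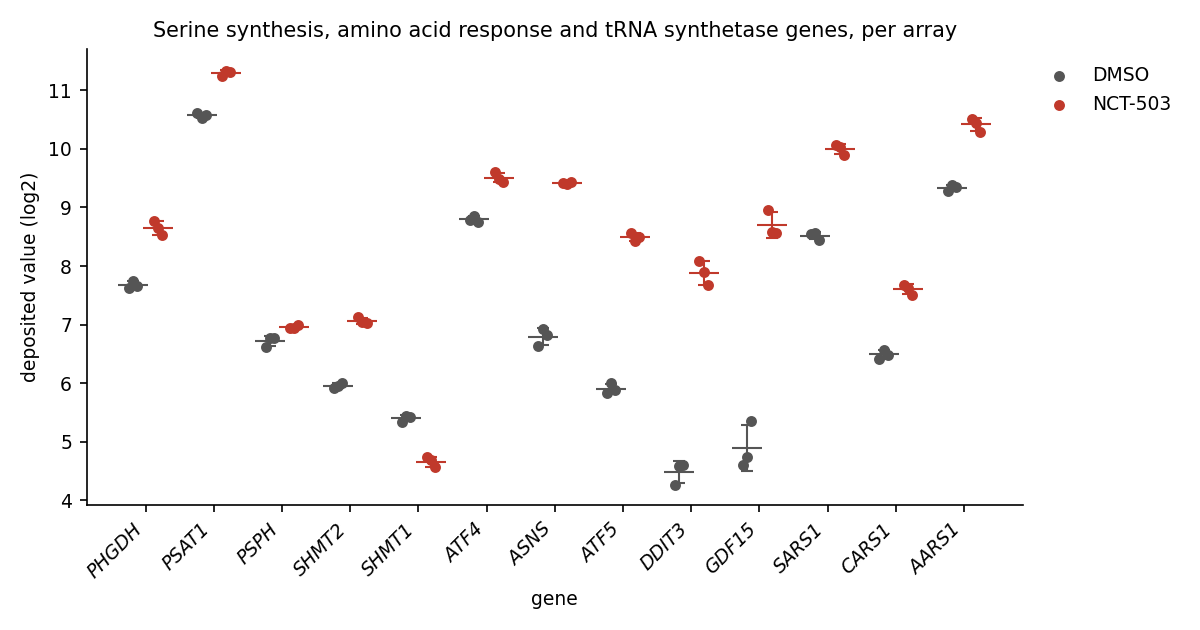
Deposited log2 values (vertical axis) of 13 genes of serine synthesis, the amino acid response and tRNA charging (horizontal axis); each point is 1 array, and the dashes and bars are the mean and SD of 3 arrays per group, DMSO in grey and NCT-503 in red. For each gene shown, the 3 NCT-503 values lie apart from the 3 DMSO values, below them for SHMT1 and above them for the other genes. Of the 14779 genes tested, 7073 (47.9%) had no overlap between the groups, so such separation is not particular to the genes shown.

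ATF4 is the transcription factor of the amino acid and integrated stress response. It rose by 0.71 ± 0.08 (adjusted p = 0.000607), and 19 of the 23 measured members of the ATF4 target list rose (21 rose and 2 fell when adjusted over the list alone). GDF15, a stress-induced cytokine, rose 14.01-fold (3.81 ± 0.21, adjusted p = 4.62e-05). DDIT3, which encodes the stress factor CHOP, rose 10.6-fold, ASNS, asparagine synthetase, rose 6.17-fold, and ATF5 rose 6.03-fold. Members that did not pass were FGF21 (0.43), KLF4 (0.42), VLDLR (-0.20) and TXNIP (-0.21). The list was called higher (median change 0.82, adjusted p = 8.96e-10), with an adjusted p of 0.100 with an estimated correlation.

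In the list of cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 16 of 18 measured members rose (17 adjusted over the list alone). These counts include AIMP1 (0.39, called higher), a partner protein of the synthetases that charges no tRNA. SARS1, which charges serine tRNA, rose most (2.79-fold, 1.48 ± 0.08, adjusted p = 4.62e-05), followed by CARS1 (2.17-fold), AARS1 (2.11-fold) and WARS1 (1.92-fold). Their list was called higher (median change 0.59, adjusted p = 6.59e-08), with an adjusted p of 0.108 with an estimated correlation. No member of the fixed list of amino acid transporters was analysed here.

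Heat shock genes rose in 7 of 11 measured members, also when adjusted over the list alone. The near-identical HSPA1A and HSPA1B, which the probes may not separate, rose 2.51-fold and 2.62-fold, and the heat shock factor HSF1 rose 1.83-fold. Camera called this list higher (median change 0.57, adjusted p = 0.000252; adjusted p = 0.100 with an estimated correlation). Among endoplasmic reticulum chaperones and unfolded protein response genes, 7 of 15 rose, also adjusted over the list alone. They were led by the sensors and effectors XBP1 (2.60-fold), ERN1 (2.51-fold), SEL1L (1.74-fold) and ATF6 (1.44-fold). That list was called higher (median change 0.15, adjusted p = 0.0374; adjusted p = 0.349 with an estimated correlation). Its call was lost without DMSO c (adjusted p = 0.0574), NCT-503 a (0.0557) or NCT-503 b (0.0517), and on quantile-normalised arrays (0.0714).

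Autophagy and lysosome genes rose in 14 of 28 measured members and fell in 2, ATG5 and ATG16L1 (16 and 3 adjusted over the list alone). GABARAPL1 and MAP1LC3B, whose products coat autophagosomes, rose 2.46-fold and 2.25-fold, and the lysosomal enzymes NEU1 and CTSB rose 1.84-fold and 1.70-fold. The list was called higher (median change 0.36, adjusted p = 0.00135; adjusted p = 0.280 with an estimated correlation). In the BCL2 family, which controls apoptosis, 7 of 14 rose (8 adjusted over the list alone). The survival gene BCL2 rose 2.24-fold, and the death-promoting BMF and PMAIP1 rose 2.14-fold and 1.57-fold. The BCL2 family was called higher as a list (median change 0.34, adjusted p = 0.0216; adjusted p = 0.178 with an estimated correlation).

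Of 32 measured genes of DNA replication and the G1/S transition, 29 fell (30 adjusted over the list alone) and 1 rose, CDT1, a replication licensing factor, with a change of 0.56. CCNE2, a cyclin of the G1/S transition, fell by 2.49 ± 0.15 (adjusted p = 5.61e-05), PCNA, the sliding clamp of replication, by 2.04 ± 0.09 (adjusted p = 1.66e-05), the flap endonuclease FEN1 by 1.81 ± 0.10 and the licensing factor CDC6 by 1.63 ± 0.09. The replication list was called lower (median change -1.05, adjusted p = 9.23e-18), with an adjusted p of 0.0513 with an estimated correlation. Of 46 measured genes of mitosis and G2/M, 35 fell (38 adjusted over the list alone) and 3 rose, BUB3, TTK and NEK2. CENPA, the centromeric histone, fell by 1.28 ± 0.09, the kinesins KIF23 and KIF14 by 1.28 ± 0.07 and 1.22 ± 0.10, and the proliferation marker MKI67 by 1.17 ± 0.07. This list too was called lower (median change -0.53, adjusted p = 4.95e-13; adjusted p = 0.0676 with an estimated correlation). Among G1 cyclins, kinases and inhibitors, RBL1 (-1.10), E2F3 (-0.71), CDK2 (-0.68) and CCND1 (-0.34) fell of 11 measured, also adjusted over the list alone. That list was not called by camera (adjusted p = 0.121), though its adjusted p was 0.0453 in camera with a trend.

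**Figure D2:**
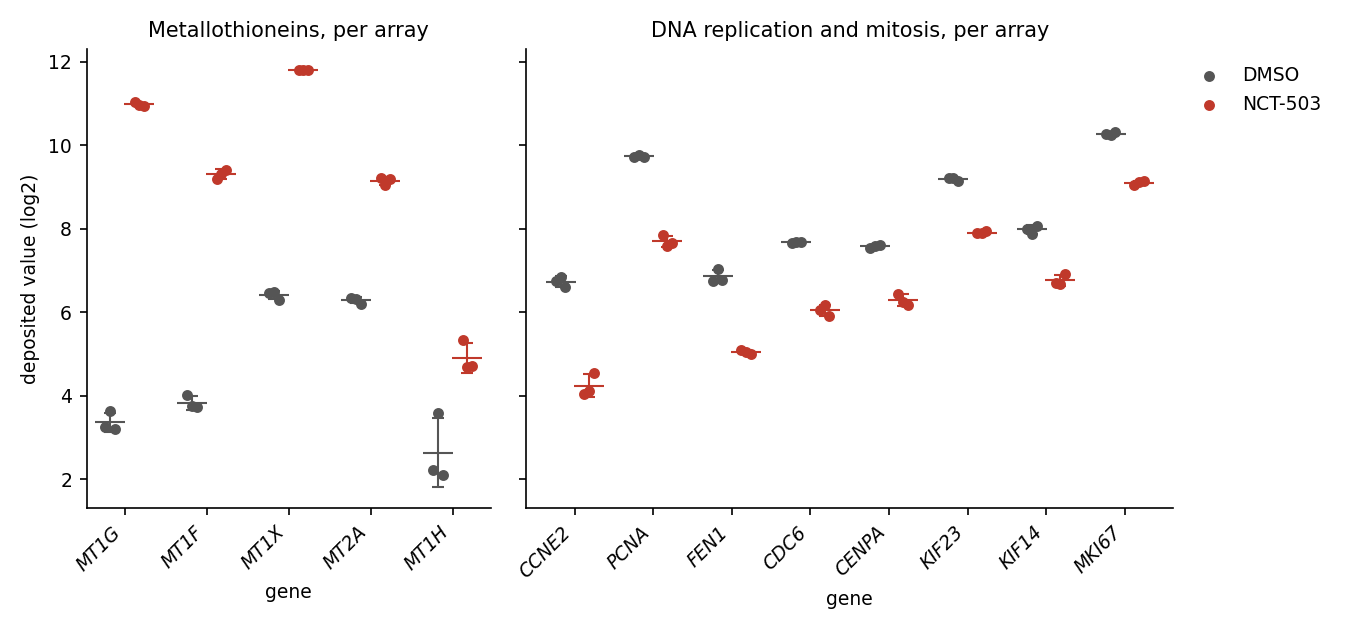
Deposited log2 values (vertical axis) of 5 metallothionein genes (left) and 8 genes of DNA replication and mitosis (right); each point is 1 array, and the dashes and bars are the mean and SD of 3 arrays per group, DMSO in grey and NCT-503 in red. MT1G stood at 3.37 in DMSO and 10.98 in NCT-503 on average, and PCNA at 9.74 and 7.70.

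Folate metabolism carries the carbon units that serine supplies. Of 11 measured members, 5 fell, DHFR2 (-0.75), MTFMT (-0.73), TYMS (-0.68), MTRR (-0.65) and MTR (-0.52), and 3 rose and 5 fell when adjusted over the list alone or with arrays centred on the median or the 75th percentile. The list was not called (median change -0.03, mean -0.20, adjusted p = 0.204), and its median was above 0 under each of the other scalings (0.01 to 0.06). MTRR lost its call without DMSO b, DMSO c, NCT-503 a or NCT-503 b (adjusted p from 0.0623 to 0.0673). Purine and pyrimidine synthesis had 9 falls and 4 rises among 24 members (10 and 6 adjusted over the list alone, 8 and 6 with arrays centred on the median or the 75th percentile), with falls of UMPS (-1.23 ± 0.08), RRM2 (-1.11 ± 0.07) and PFAS (-0.79 ± 0.12), and was not called (adjusted p = 0.202).

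Methionine cycle, transsulfuration and glutathione genes went both ways, 5 higher and 2 lower of 19, also adjusted over the list alone. CTH, cystathionine gamma-lyase, rose 2.01-fold, GPX4 1.63-fold and GSR 1.32-fold, and CBS fell by 0.48 ± 0.07. Camera did not call the list (median change 0.13, adjusted p = 0.447). Of 12 NRF2 target and oxidative stress genes, 6 rose and 1 fell, also adjusted over the list alone, among them TKT (1.67-fold), NFE2L2 (1.55-fold) and CAT (0.58 ± 0.07 on the log2 scale), with no call of the list (adjusted p = 0.106).

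Cytosolic ribosomal protein genes rose in 21 of 44 members (28 adjusted over the list alone), in 29 with arrays centred on the median and in 32 with arrays centred on the 75th percentile, whereas RPS26 fell (-0.46). RPS7 rose 2.13-fold (1.09 ± 0.10, adjusted p = 0.000308), RPL36 1.72-fold and RPS15A 1.64-fold, and the list was called higher (median change 0.26, adjusted p = 2.21e-06; adjusted p = 0.338 with an estimated correlation). Ribosome biogenesis and MYC target genes fell in 9 of 25 members and rose in 3, also adjusted over the list alone (8 and 6 with arrays centred on the 75th percentile). NIP7, NOP2 and NOP58, factors of ribosomal RNA processing, fell by 0.80 ± 0.07, 0.65 ± 0.08 and 0.62 ± 0.08, and NOB1, which acts in small-subunit maturation, rose by 1.07 ± 0.10. That list was not called (median change -0.03, adjusted p = 0.202), and its median was above 0 with arrays centred on the median or the 75th percentile (0.01 and 0.04).

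Of the 50 fixed nuclear-encoded respiratory chain genes, 15 were measured, all of them UQCR, CYC1 or COX genes. No NDUF or ATP synthase gene of the list was measured, so the result does not cover the whole chain. Of the 15 measured, 10 rose (12 adjusted over the list alone), led by UQCRB (1.47-fold), COX5B (1.38-fold) and UQCRC2 (1.37-fold). The list was called higher (median change 0.30, adjusted p = 0.000856; adjusted p = 0.338 with an estimated correlation). In the tricarboxylic acid cycle 3 of 11 rose and 1 fell, also adjusted over the list alone. IDH3B rose 1.41-fold, and the list was not called (adjusted p = 0.404). Glycolysis genes had 1 rise, of HK1 (0.43 ± 0.09), and 1 fall, of HK2 (-0.40 ± 0.10), among 8, also adjusted over the list alone. The HK2 call was lost without NCT-503 a (adjusted p = 0.0526) or NCT-503 c (0.0534), and the list was not called (adjusted p = 0.522).

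Lipid synthesis genes split. Of 19 cholesterol synthesis and uptake genes 7 rose, also adjusted over the list alone, with INSIG1 at 3.05-fold (1.61 ± 0.10, adjusted p = 7.15e-05), MSMO1 at 2.25-fold and MVK at 1.56-fold. The cholesterol list was called higher (median change 0.15, adjusted p = 0.0356; adjusted p = 0.359 with an estimated correlation). Of 15 fatty acid synthesis genes 6 fell and 3 rose (8 and 3 adjusted over the list alone). The acetyl-CoA carboxylases ACACA and ACACB fell by 0.84 ± 0.07 and 0.65 ± 0.08, the elongase ELOVL6 fell by 0.66 ± 0.08, and ACSL4 rose by 0.63 ± 0.08. The fatty acid list was called lower (median change -0.20, adjusted p = 0.0423; adjusted p = 0.230 with an estimated correlation). The cholesterol call was lost without DMSO c (adjusted p = 0.0552) or NCT-503 a (0.0994), and without NCT-503 a its median change was only 0.054. The fatty acid call was lost without DMSO a (0.0748), DMSO c (0.0558) or NCT-503 a (0.0678). Sphingolipid synthesis had 3 rises and 1 fall among 12 genes, also adjusted over the list alone, with CERS2 at 1.48-fold and CERS4 at 1.41-fold, and was not called (adjusted p = 0.663).

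Neuroblastoma cells occupy adrenergic or mesenchymal states defined by their transcription factors. Among 20 adrenergic transcription factors, 8 fell and 4 rose (9 and 4 adjusted over the list alone). TFAP2B fell by 1.44 ± 0.08 (adjusted p = 4.44e-05), MEIS2 by 1.24 ± 0.07 and DACH1 by 1.16 ± 0.09, and TBX2 rose by 0.93 ± 0.09. Camera did not call the adrenergic list (median change -0.14, adjusted p = 0.202). Among 23 mesenchymal and neural crest-like genes, 9 rose and 1 fell, also adjusted over the list alone. SNAI1 rose 2.75-fold (1.46 ± 0.09, adjusted p = 7.52e-05), vimentin (VIM) 2.18-fold, SNAI2 2.10-fold and HEY1 1.69-fold. The mesenchymal list was called higher (median change 0.26, adjusted p = 0.0234; adjusted p = 0.178 with an estimated correlation).

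Catecholamine and noradrenergic neuron genes went both ways, 7 higher and 4 lower of 15, also adjusted over the list alone. The granins CHGA and CHGB fell by 1.23 ± 0.09 and 1.13 ± 0.08, and SCG2 and NPY rose by 1.11 ± 0.08 and 0.80 ± 0.13. The median of the list was 0.08 and its mean was -0.003, so these differed in sign, and the list was not called (adjusted p = 0.995). Neuronal differentiation markers rose in 5 of 20 and fell in 1, also adjusted over the list alone (8 and 0 with arrays centred on the 75th percentile), with PRPH at 3.02-fold, SYN1 at 1.77-fold and VAMP2 at 1.48-fold, and no call of the list (adjusted p = 0.202). Of 7 Schwann and glial markers, NGFR, a neurotrophin receptor that neural crest cells also express, rose 4.12-fold and MBP 1.56-fold (4 rose when adjusted over the list alone or with arrays centred on the median or the 75th percentile), while SOX10 (0.14) and S100B (-0.18) did not pass, and the list was not called (adjusted p = 0.150).

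Immediate early genes rose in 9 of 25 and fell in 1 (10 and 1 adjusted over the list alone). SPRY4 rose 3.23-fold, DUSP4 2.32-fold, EGR1 2.21-fold and ATF3 1.89-fold, and the list was called higher (median change 0.24, adjusted p = 0.0155; adjusted p = 0.166 with an estimated correlation). Of 12 p53 target genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone). TP53INP1 fell by 1.09 ± 0.12, TIGAR by 1.05 ± 0.15 and AEN by 0.84 ± 0.08, and PLK3 rose by 0.78 ± 0.09. The p53 list had a median of 0.06 and a mean of -0.04, which differ in sign, and was not called (adjusted p = 1.00). Of 17 hypoxia targets, 8 were higher and 4 lower (8 and 5 adjusted over the list alone, 9 and 2 with arrays centred on the 75th percentile), with falls of STC1 (-1.76 ± 0.07) and HILPDA (-1.54 ± 0.08) and rises of ADM (2.59-fold) and VEGFA (1.80-fold), and no call of the list (adjusted p = 0.670).

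DNA and histone methyltransferases use the methyl donor that the methionine cycle regenerates. The fixed list of DNA and histone methylation enzymes also holds demethylating enzymes (TET and KDM genes), which do not use it. Of 19 measured members of this mixed list, 8 fell and 3 rose (10 and 3 adjusted over the list alone). KMT2D fell by 0.83 ± 0.07, NSD2 by 0.69 ± 0.08, DNMT3B by 0.59 ± 0.13 and DNMT1 by 0.56 ± 0.08. The list was called lower (median change -0.21, adjusted p = 0.0171; adjusted p = 0.266 with an estimated correlation). No member of the fixed list of replication-dependent histones was analysed here.

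Of 19 interferon-stimulated genes, CXCL10 (0.36) rose and ISG20 (-0.49) fell, but neither passed when adjusted over the list alone. CXCL10 lost its call without DMSO a, DMSO b, NCT-503 b or NCT-503 c (adjusted p from 0.0526 to 0.0629), and ISG20 without each array except DMSO c (0.0608 to 0.0894). The interferon list was not called (adjusted p = 0.586). Among 7 immune and endothelial markers, CD68, a lysosomal glycoprotein of macrophages, rose 4.76-fold (2.25 ± 0.10, adjusted p = 1.53e-05), and CD14 (-0.09), CSF1R (0.13), LYZ (0.09), VWF (0.01) and KDR (0.07) did not pass. NKG7 rose by 0.41 ± 0.12 and lost this call without DMSO a, DMSO b, NCT-503 a or NCT-503 b (adjusted p from 0.0941 to 0.104). These 2 rises held when adjusted over the list alone, and the list was not called (adjusted p = 0.209).

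Lists with fewer than 5 measured members were not tested as lists. Of 3 xenobiotic and AHR response genes, TIPARP rose 2.44-fold and ARNT 1.48-fold. Of 3 antigen presentation genes, B2M rose by 0.32 ± 0.08 and ERAP1 by 0.30 ± 0.08, and both lost their call without DMSO a, DMSO c, NCT-503 a or NCT-503 b (adjusted p from 0.0556 to 0.0812 and from 0.0548 to 0.100), and ERAP1 also without NCT-503 c (0.0773). Of 4 cholesterol efflux and LXR target genes, LPCAT3 fell by 0.80 ± 0.08, SREBF1 fell by 0.51 ± 0.10, and APOE rose by 0.78 ± 0.14. Of 4 fibroblast and collagen markers, DCN fell by 0.47 ± 0.09 and THY1 by 0.25 ± 0.08, and THY1 lost its call when any 1 of the 6 arrays was left out (adjusted p from 0.0652 to 0.117) and under each other scaling. Adjusted over the list alone, these calls were the same in number except for the fibroblast markers, where 3 fell.

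**Figure D3:**
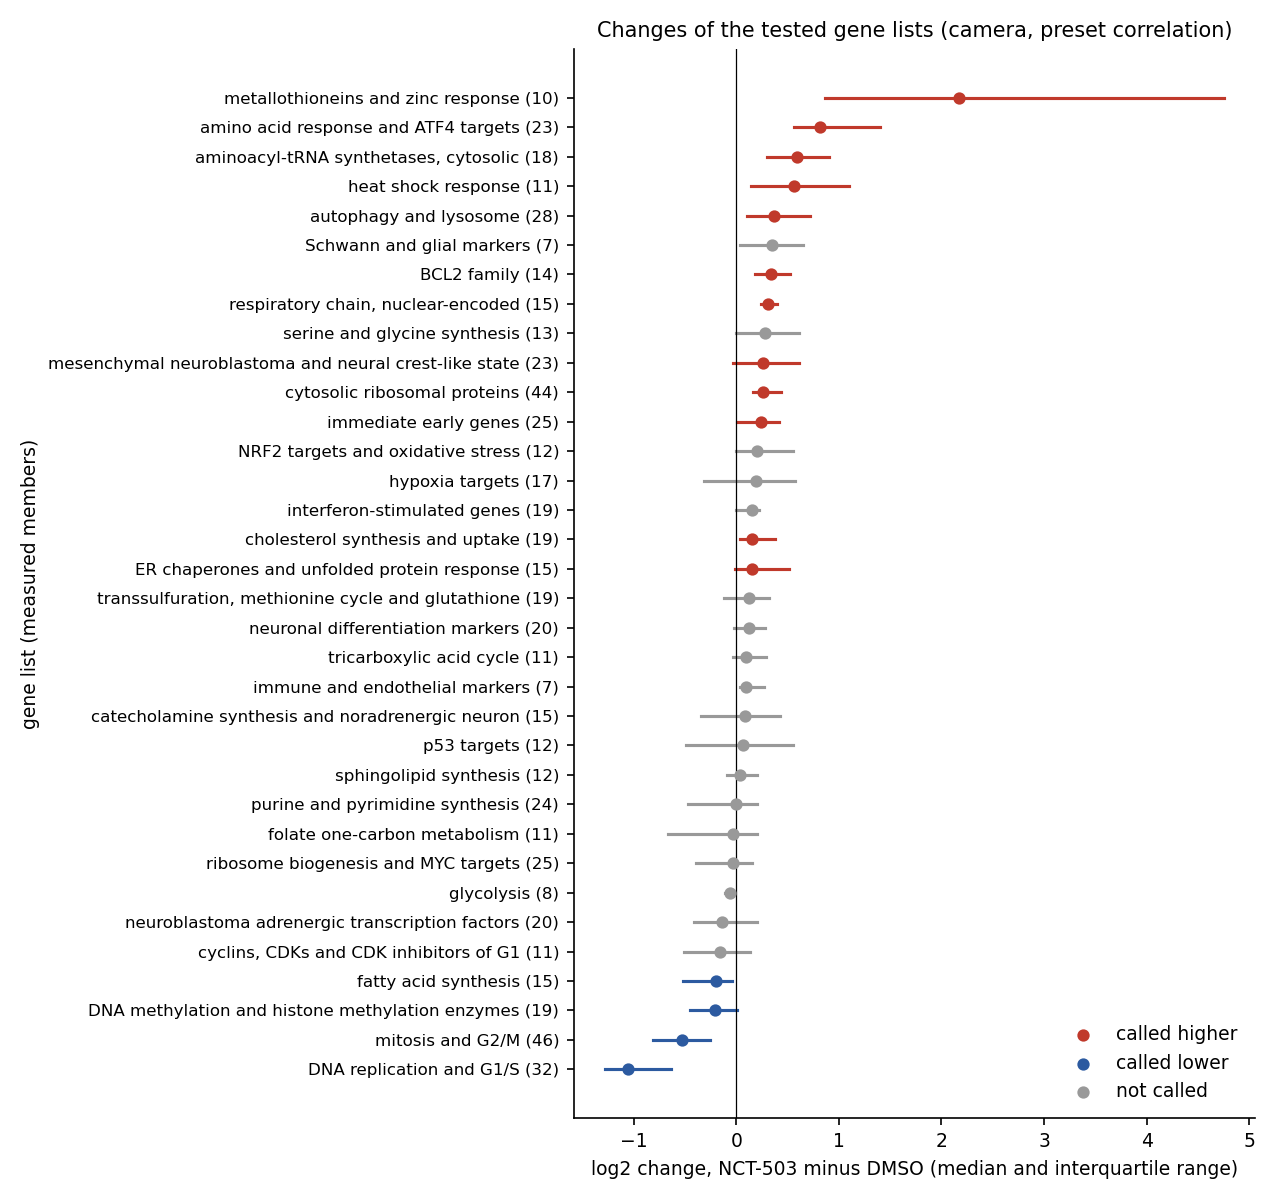
Log2 change, NCT-503 minus DMSO (horizontal axis), of the members of each of the 34 tested gene lists (vertical axis, measured members in parentheses); the point is the median and the bar the interquartile range over genes. Red lists were called higher, blue lists were called lower and grey lists were not called by camera with a preset correlation; medians run from -1.05 for DNA replication and G1/S to 2.17 for metallothioneins.

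Across the 34 tested lists camera called 12 higher and 4 lower with a preset correlation, and 0 with an estimated correlation, where 9 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.0513. The test fry, which asks whether a list moves without setting it against other genes, called 29. Some genes belong to more than 1 list.

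Outside the lists, ARRDC3 rose 5.51-fold, CREBRF, a regulator of the unfolded protein response, 5.31-fold, and ULBP1, a ligand of the natural killer cell receptor NKG2D, 4.95-fold. Among the genes that the naming rule covers, the largest falls after MINAR2 (-3.76 ± 0.08, adjusted p = 1.03e-06) were those of ZAR1 (-2.87 ± 0.17), ZNF429 (-2.81 ± 0.15), DGCR8, a cofactor of microRNA processing (-2.74 ± 0.15), and FLRT3 (-2.73 ± 0.14). Several microRNA loci, which the rule leaves out, fell further than MINAR2. ZNF480, NCOA5, RBBP6, RTL1 and LCMT2 fell by 2.14 to 2.57 on the log2 scale. ZNF224 fell by 2.41 ± 0.14 on its brighter row, and its other row had a difference of 0.13 (adjusted p = 0.422), so the rows of this gene disagree. By annotated class, 2191 protein-coding genes were higher and 2077 lower of 11891, and 67 microRNA loci were higher and 163 lower of 1020.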

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

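Rows without a gene name were fitted as planned, and no test of an explanation was run on them. Of 16037 rows of the array without a gene name here, outside the comparison of named genes, 3273 changed between NCT-503 and DMSO in a limma fit of every row (1526 higher, 1747 lower). At least 2-fold changes numbered 112 higher and 463 lower. The rows with the largest changes, listed by their probe set numbers, were 16819244, which rose from 7.25 to 11.4, and 16858210, which rose from 7.37 to 10.6, and 16788703, which fell from 9.20 to 4.81, and 16788701, which fell from 9.09 to 5.06 (means of log2 values over 3 arrays each). They were picked after their values were seen, and no gene was assigned to them. By number, 16788701 and 16788703 lie between the rows of MIR370 and MIR379, and 16819244 lies between those of MT2A and MT1F. Whether these rows are separate from the metallothionein and microRNA loci described elsewhere was not tested.

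The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4953 genes and 2043 with at least a 1.5-fold change, and the highest of the other splits was 0 for both (limma; 317 genes at an unadjusted p under 0.05, against 6474 in the real split). For gene lists the real split called 16 and the highest other split 8 with camera's preset correlation. In each of these cases 1 split, the real one, gave as many calls. Each other split puts arrays of both groups on each side, so the difference between the groups adds to its spread. Low counts of gene calls there were therefore built in. The splits cannot decide whether the grouping accounts for the calls, and no conclusion is drawn from them.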

How the results depend on the processing

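Of 153 named genes, none changed sign where it was called, over 19 alternatives, and 22 lost their call in at least 1. Of the 4953 calls, an adjusted p under 0.01 kept 58.7%, and the other settings that tested each of these genes kept 74.9% to 99.5%. The filters at the 25th and 50th percentile and protein-coding genes alone, an alternative chosen after seeing the data, still tested 4567, 3710 and 4268 of them, which stayed called. Testing each of the 31135 rows, 16037 of them without a gene name, gave 3621 rows higher and 4100 lower, 1250 and 2462 of them by at least 1.5-fold. An adjusted p under 0.01 left 1226 genes higher and 1682 lower, and 7 lists higher and 2 lower. The filter at the 50th percentile left 2 lists lower. An estimated correlation left 0 lists higher and 0 lower, where 9 had an unadjusted p under 0.05. It ended the calls of ATF4 targets (0.82, adjusted p = 0.100), DNA replication (-1.05, 0.0513) and mitosis (-0.53, 0.0676). The fry test, which sets no list against other genes, called 20 lists higher and 9 lower. It added serine and glycine synthesis (0.28, adjusted p = 0.000195), folate (-0.029, 0.000141), ribosome biogenesis (-0.034, 0.000935) and adrenergic factors (-0.14, 0.000195). Serine and glycine synthesis also passed in camera with a trend (0.28, 0.0297), as did the G1 cyclin and kinase list (-0.16, 0.0453). The robust setting entered only the gene fit, not the list test. Serine and glycine synthesis passed with the 25th percentile filter too (0.35, 0.0404), and the cause was not tested. Leaving out 1 array gave 1749 to 2100 genes higher, 2103 to 2266 lower, 10 to 12 lists higher and 3 or 4 lower. The calls of fatty acid synthesis, cholesterol synthesis and the unfolded protein response were lost in some of these and on ranks (adjusted p = 0.0704, 0.0599 and 0.0730). Protein-coding genes alone ended the cholesterol (0.0531) and unfolded protein response (0.0537) calls. The fatty acid call was lost with the 25th and 50th percentile filters (0.0982 and 0.184), and those of the mesenchymal, BCL2 and methylation enzyme lists with the 50th percentile filter (0.122, 0.0803 and 0.111). The letters of the replicates did not pair the samples (correlations of deviations 0.00361, 0.00263 and 0.0375 for a, b and c), and a replicate block gave 4435 gene calls and did not call fatty acid synthesis or the unfolded protein response (adjusted p = 0.0596 for both). The pseudocount was not run, as the table is on a log scale, and lists have no test without moderation. Signal over background was not analysed here.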

Other observations

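The gene families and tests in this part were chosen after the values were seen. The p-values of the families come from those same values and were adjusted over the 6 families tested alone. They describe the families, are not tests of a prior hypothesis, and cannot be set against those of the fixed lists. Of 10 SR splicing factors, 7 were lower, 1 was higher (SRSF12) and 2 were not called, with SRSF1 at -1.75 (adjusted p = 1.20e-05) and SRSF6 at -1.68 (3.73e-05), and the family was called lower by camera, with an adjusted p of 0.0234 with an estimated correlation, over the 6 families tested. Of 21 heterogeneous nuclear ribonucleoproteins, 9 were lower, 1 was higher (HNRNPLL, 0.71) and 11 were not called, with HNRNPAB at -1.18 and HNRNPM at -1.16 (adjusted p = 0.0352 with an estimated correlation). The CDC-like kinases, which phosphorylate SR proteins, went the other way in 3 of 4 cases: CLK1 rose by 1.17, CLK4 by 1.20 and CLK3 by 1.01, while CLK2 fell by 0.40. The medians of these families kept their sign under each scaling tried.

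All 5 measured E2F factors fell (median change -1.13, adjusted p = 0.0234 with an estimated correlation), E2F7 most (-2.01), and so did 11 of 16 centromere proteins (median -0.48, adjusted p = 0.0142 with an estimated correlation). E2F1, E2F2 and E2F8 also belong to the fixed replication list, E2F3 to that of G1 cyclins, kinases and inhibitors, and CENPA and CENPK to the mitosis list. These families are therefore not independent of the fixed lists, and E2F7 is the only measured E2F factor outside them. Of 71 mitochondrial ribosomal proteins 27 rose and 6 fell (median 0.15, adjusted p = 0.383 with an estimated correlation).

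On chromosome 14, 49 of 51 measured microRNA loci between the noncoding genes MEG3 and MEG9 fell and the other 2 were not called in limma, with a median change of -2.41, against 114 lower and 67 higher of 969 microRNA loci elsewhere. Mature microRNAs were not measured apart from longer transcripts of the same loci. Neighbouring loci may share a transcript, so the 51 are not separate observations. Loci of the same class elsewhere matched on mean level had a median change of -0.00976 over 10000 draws (lowest draw -0.285), which argues against lower signal from microRNA probe sets in general. The draws took loci independently, so their range does not allow for shared transcripts. The other genes of the stretch fell too (MEG3 -1.44, RTL1 -2.19 on its brighter row, MEG9 -0.85), with a median of -1.44. The other row of RTL1 changed by -2.95. Whether either row reads RTL1 or transcripts of the microRNA loci was not tested. The 10 flanking measured genes had a median of 0.06, with DLK1 lower (-0.36) and WARS1 higher (0.94). Less RNA from the whole stretch may therefore account for the fall, as a hypothesis found and tested on the same values. Whether transcription or RNA turnover changed stays open, and so does the effect of the treatment that separates the groups.

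Of 467 zinc finger genes with ZNF symbols, 196 fell and 52 rose, with a median change of -0.23, which stayed below 0 under each scaling tried (-0.19 to -0.16 in the others; adjusted p = 0.00540 with an estimated correlation). Protein-coding genes matched on mean level had a median of 0.049 over 10000 draws, and the lowest draw was -0.042, which argues against a shift of the arrays that depends on signal level. The 242 zinc finger genes on other chromosomes than 19 had a median of -0.177 (93 lower, 28 higher), which argues against a change confined to the clusters on chromosome 19, where 225 genes had a median of -0.29. Cross-hybridisation between these paralogs was not tested, because probe sequences were not used here, and an effect of the treatment may remain as an untested explanation.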
